A study of Mus musculus with 10 samples.

How the data were processed

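Single-nucleus ATAC-seq measures where Tn5 can insert adapters, and so where chromatin is open, in each of many nuclei. Frozen C57BL/6 mouse embryos at embryonic day 8.25 were thawed, and 10 of them were pooled. Per the labels, 1500 nuclei per well were tagmented in 2 plates of 96 wells, nuclei were stained with DRAQ7, and 40 nuclei per well were sorted into 6 plates for barcoding by PCR, with extra plates for small and for large nuclei. Libraries were sequenced in 3 NextSeq500 runs and 1 HiSeq2500 run. The 3 samples of each gate are runs of the same pool and count as 1 sample. The sample without a sorting label could not be separated in the deposited tables and enters no group.

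The submitters' notes name Bowtie2, SAMtools, MACS2 2.1.0.20150420, bedtools and Scanpy 1.4.4 and the genome build mm10 (GRCm38), without the order or role of the tools. The main table holds deposited counts, that is unnormalised reads per OCR and barcode, with runs and gates merged. Of its non-zero entries 72.3% were 2, 18.5% were 1 and 9.21% were larger, so reads mostly come in pairs from the same fragment. A table of nuclei made by the authors gives the label (all, 2n or 4n), the cell type, the subcluster of allantoic, endothelial and erythroid nuclei, a doublet score whose caller is not stated, and the fraction of reads in peaks. The deposited topic values are fractions of each nucleus, which sum to 1, and were multiplied by 100. The chromVAR values deposited per motif and nucleus are a score, between -11.7 and 29.6 with an SD of at least 0.765 for every motif. Whether they are deviations or z-scores is not stated, so differences and SDs are given and no folds. The authors' table of OCRs gives the annotation class, the paired genes and the types in which they call an OCR specific, and its other columns are names and classes without a unit. No column of values per sample was left unused.

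All 19453 annotated nuclei were used, and no nucleus was removed for its doublet score except in a named alternative. The 4385 barcodes without a type (median 6369 reads in OCRs, against 8248) enter the closing part alone. The reads in OCRs per annotated nucleus ranged from 793 to 95187. By label, 133900943 reads belonged to nuclei labelled all, 19271349 to 2n and 25188577 to 4n. The labels occupied 576, 96 and 96 PCR barcodes with none in common, and shared the 192 tagmentation barcodes. Reads were summed over the nuclei of a type and scaled to CPM, the count per 1000000 reads in OCRs of the type. With 1 pooled sample there are no p-values and no standard errors over nuclei, since nuclei are not replicates. Rules of size were fixed before the data were examined in place of tests.

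A type differed by label when its share among 4n nuclei was at least 1.5 times that among 2n nuclei or the reverse. The ratio of median reads was taken over all nuclei and in types with at least 50 nuclei under both labels. A gene's value is log2 of (CPM in the type + 1) over (CPM in all other nuclei + 1), summed over the OCRs that the authors pair with it, and a list's value is the median over its genes. The 23 lists of 6 to 10 genes were 17 lists named after an annotated type, a list for intermediate and lateral plate mesoderm, lists for primordial germ cells, trophoblast, megakaryocytes and macrophages, and parietal endoderm, and a housekeeping list. For these other lists the type with the highest median is reported. Random lists (10000 each) were matched in size and, over 50 bins, in mean CPM. The 29 motif groups were fixed by factor symbol, a group's value being the median over its motifs of the mean score in a type minus that in all other nuclei. In all, 6 listed factors had no motif among the 884, among them Tbx6, whose group has no value. An OCR was type-specific when at least 5% of the type's nuclei had a read and its CPM was at least 4 times that of all other nuclei. The 11 pairs of types used the same bounds between both types. A topic was led by a type when its mean there was at least 4 times that in all other nuclei.

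Genes and OCRs to name were also chosen by a rule fixed before the data were examined. For each gene list these are the 3 genes with the highest log2 fold in the type and the lowest, for each type the OCR with the highest fold among those with a read in at least 10% of its nuclei and the 3 motifs with the highest difference, for each pair the 2 OCRs with the highest ratio each way, every type past the rule for labels, and the leading topic of each type. Some genes, OCRs and motif groups that this rule picks are not reported here. Genes named in the pairs are members of the fixed lists, picked after their values were seen, and so are the genes named by subcluster. Intervals for shares are exact Clopper-Pearson intervals. Those for folds are exact conditional intervals after the reads were divided by 2 and rounded up, since reads come in pairs. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Where the other group had no read the fold is set against a floor of 3 counts over the group, and the lower bound is the lower end of the interval.

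The rules were tested on simulated data made from the pooled reads of these OCRs. This test was written and first run after the main values had been computed and seen, and no rule was changed after it. Counts were drawn per OCR and type at the type's total of reads, and no single nuclei were simulated. Each read pair was counted as a nucleus of its own, up to the type's number of nuclei. Of 200 OCRs raised 2-fold or 3-fold in counts drawn for Endothelium, 0 met the rule at either fold, and all 200 met it at 6-fold and 8-fold. For Notochord 0.500%, 10.5%, 95% and 99.5% met it at 2, 3, 6 and 8-fold. A raised OCR also had to reach the share of nuclei that the rule asks for. All 200 did so at 6-fold in Endothelium, so they were OCRs read often enough for such a rise to pass that bound. The test therefore shows how the bound on fold acts in such OCRs. It does not give the recovery of OCRs that are rarely read in other nuclei. With nothing raised, 40 of 305187 OCRs met it for Notochord, 8 for ExE endoderm and 0 for each of the other 16 types. Variation between nuclei was left out, so these numbers need not hold for the real nuclei. A list raised 2-fold was recovered at a median of 0.99 and 0.89 log2 in counts drawn for Endothelium and Notochord. Motifs raised by 1 were recovered at 1.00, which the adding itself fixes, so it checks the computation alone.

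Alternatives fixed before the data were examined were a minimum of 2000 reads, leaving out the 10% of nuclei with the highest doublet score, a ratio bound of 2, odd and even tagmentation barcodes, autosomal OCRs, the binary table, equal weights for the other types, pseudocounts of 0.1 and 5 CPM, promoter or other OCRs alone, CPM over promoter OCRs, each label alone, the median over nuclei, bounds of 2% and 10% of nuclei and of 2 and 8-fold, the highest other type as the reference, and thinning. Alternatives added after seeing the data were the leaving out of nuclei with high doublet scores for OCRs and motifs and the demand that the OCR rule hold in both barcode sets. Subclusters, with the genes and the RUNX motif group read in them, were also chosen after seeing the tables. After a first run of the main values was seen, resampling intervals for the ratio of median reads were dropped, halved reads were rounded up rather than to the nearest whole number, the floor was limited to groups without a read, and motif factors known only by protein were given gene symbols. The planned text spoke of fragments, and reads were used because the table holds reads. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, PyArrow 21.0.0 and Matplotlib 3.10.9 were used. OCR positions are in GRCm38 with the start counted from 1. Raw reads were not used here.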

Results

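Chromatin accessibility was measured nucleus by nucleus in whole C57BL/6 mouse embryos at embryonic day 8.25, the stage at which the heart tube, somites and neural folds form. Nuclei of 10 embryos were pooled and profiled by single-nucleus ATAC-seq, in which the transposase Tn5 inserts barcoded adapters into open DNA. Barcodes were added by tagmentation and again by PCR, so that each nucleus carries a combination of both. DRAQ7-stained nuclei were sorted into PCR wells through 3 gates, a gate for all nuclei, a gate for small nuclei and a gate for large nuclei. Each gate has 3 samples, which are sequencing runs of that gate, and 1 further sample has no sorting label. The deposited count table merges the runs and gates, so the study amounts to 1 pooled sample without replicates, and every value below comes from that pool. The table covers 305187 open chromatin regions (OCRs) and 23838 barcodes, of which 19453 carry 18 cell type names given by the authors.

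Introns held 135807 of the OCRs (44.5%), 90217 were intergenic and 53668 lay at a transcription start site (TSS). Annotated nuclei had 178360869 reads in OCRs in all, with a median of 8248 per nucleus (quartiles 5033 and 12121), in a median of 4206 OCRs. The most frequent type was NMP, the neuromesodermal progenitors that feed the spinal cord and trunk mesoderm, with 1926 nuclei, and the rarest was Notochord with 135. Extraembryonic (ExE) endoderm and Erythroid nuclei were the shallowest, with medians of 4678 and 4924 reads, and Spinal cord nuclei the deepest with 9662. Erythroid nuclei had the largest share of reads in peaks, a median of 45.5% against 34.6% over all annotated nuclei, and 52% of their reads in OCRs lay at a TSS. Intervals below are 95% intervals that cover counting error only. Outside the pairs of types, gene folds are against all other nuclei together, so a gene can be higher still in another single type.

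Sorting by nuclear size was added so that an effect of nuclear size on the analysis could be seen. In the table of nuclei the gates appear as the labels all (14655 nuclei), 2n (2443) and 4n (2355), and which of the latter is the gate for large nuclei is not stated there. ExE endoderm, the absorptive and secretory lining of the visceral yolk sac, made up 1.49% of 4n nuclei (35 nuclei, 1.04 to 2.06%, Clopper-Pearson) and 0.532% of 2n nuclei (13 nuclei, 0.284 to 0.908%), a ratio of 2.79 (1.44 to 5.75). Notochord, Gut and Cardiomyocytes were scarcer among 4n nuclei. Notochord had 21 nuclei under 2n and 5 under 4n, a ratio of 0.247 (0.0728 to 0.673). Gut had 169 and 104 nuclei, a ratio of 0.638 (0.495 to 0.820), and Cardiomyocytes 104 and 65, a ratio of 0.648 (0.468 to 0.892). The other 14 types stayed within the bound of 1.5 either way, the nearest being Surface ectoderm at 1.38 (1.13 to 1.68). The 2n and 4n nuclei occupied separate sets of 96 PCR barcodes each, so label and sorted plate cannot be told apart. With a bound of 2 in place of 1.5, ExE endoderm and Notochord alone stayed past it. At 1.5, 3 types passed without the 10% of nuclei with the highest doublet score, and 3 among odd tagmentation barcodes.

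Nuclei labelled 4n were deeper in every type with at least 50 nuclei under both labels. Their median was 9697 reads in OCRs against 7263 for 2n, a ratio of 1.34. Within the 15 types compared, the ratio ran from 1.16 in Mid/Hindbrain to 1.81 in Cardiomyocytes, with 1.62 in Pharyngeal mesoderm and 1.22 in Erythroid. The plot of type shares by label shows both the 4 types past the bound and those near 1.

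**Figure D1:**
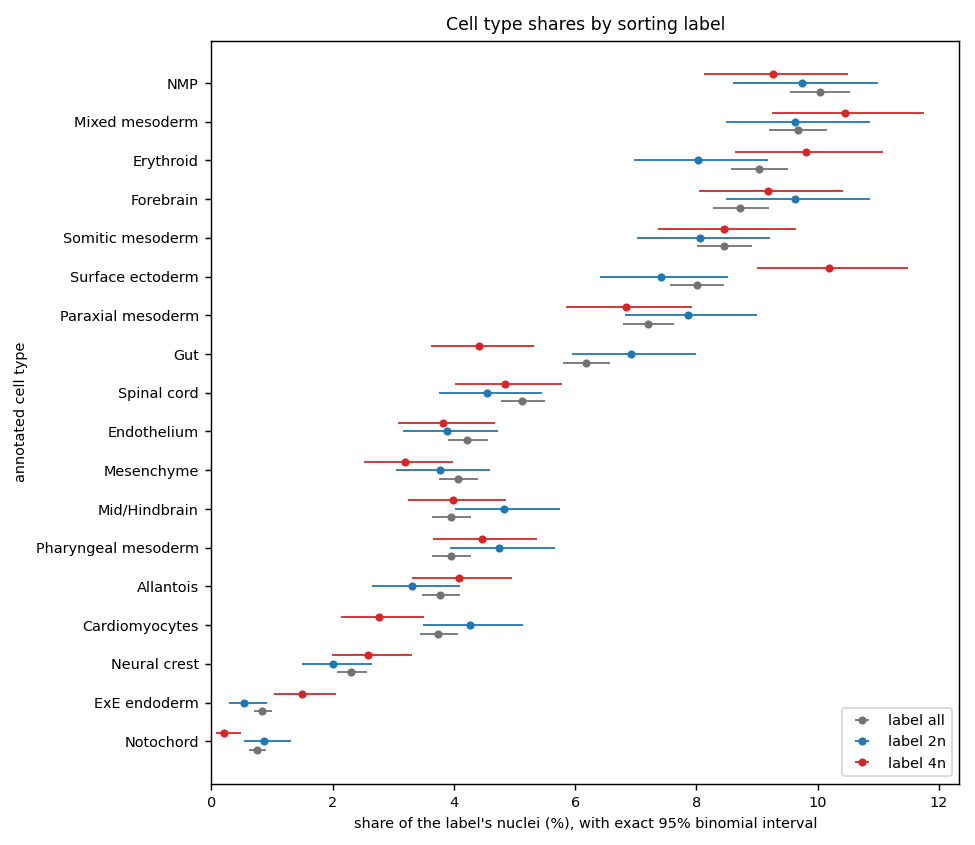
Share of annotated nuclei (%) held by each cell type among nuclei labelled all, 2n and 4n, with exact 95% binomial intervals. ExE endoderm is at 1.49% among 4n and 0.532% among 2n nuclei, and Notochord at 0.212% and 0.860%.

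Marker lists of blood, vessel and allantois had their highest medians in the types that bear these names. In Erythroid nuclei Hba-x (ENSMUSG00000055609), an embryonic alpha-like globin, had 59.99-fold (52 to 67.4) the normalised read count (CPM) of all other nuclei, summed over its OCRs. The embryonic beta-like globin Hbb-bh1 stood at 32.8-fold (24.7 to 41.7), Alas2, which starts haem synthesis in red cells, at 13.4-fold (11.7 to 15.1), and Tal1, a regulator of blood formation, was the lowest of the list at 2.99-fold (2.79 to 3.19). The list had 10 of its 10 genes above 0 and a median log2 fold of 2.51, the next type being Somitic mesoderm at -0.27. Housekeeping genes were higher in Erythroid nuclei as well, with a median of 0.62 (percentile 96.1 of random lists) and Hprt at 1.76-fold, Rpl13a at 1.70 and Pgk1 at 1.21. Scaled to promoter reads alone, the housekeeping median in Erythroid was 0.20 and that of the Erythroid list 2.13. That scaling also moved the median over all 24948 well covered genes in Erythroid from -0.12 to -0.53, and in ExE endoderm from -0.14 to -0.33.

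In Endothelium the receptor kinases Tie1 (5.65-fold (4.96 to 6.36)) and Tek (5.51-fold (5.04 to 6.00); ENSMUSG00000006386) and the VEGF receptor Kdr (4.67-fold (4.32 to 5.03)) stood highest. Sox17, a regulator shared by arteries and endoderm, was lowest at 1.83-fold (1.61 to 2.06) and was higher still in ExE endoderm. The Endothelium list had 10 of its 10 genes above 0 and a median of 1.56, with Allantois next at 0.34. A short list for megakaryocytes and macrophages was also highest in Endothelium, at 0.61, with Erythroid next at 0.44, but fell to 0.27 with promoter OCRs alone, 0.29 without them and 0.34 among 2n nuclei. Its leading gene Pf4, which encodes platelet factor 4, stood at 8.86-fold (6.65 to 11.4), Csf1r, the receptor of macrophage growth factor, which was higher still in ExE endoderm, at 2.31, Spi1 at 1.65 and Gp9 at 1.07. In Allantois, the forerunner of the umbilical cord, Tbx4 (ENSMUSG00000000094) reached 4.16-fold (3.87 to 4.46), and the posterior Hox genes Hoxa10 and Hoxa11 2.74 and 2.44. Vcam1, an adhesion protein needed to join allantois and chorion, was lowest at 1.21-fold (0.882 to 1.65). The Allantois list had 8 of its 8 genes above 0 and a median of 1.00.

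Heart muscle genes had the highest list median in mesoderm after Erythroid. In Cardiomyocytes the myosin gene Myh6 (ENSMUSG00000040752) stood at 16.1-fold (14.2 to 18), cardiac actin Actc1 at 12.8-fold (11.2 to 14.4) and titin, Ttn, at 7.05-fold (6.47 to 7.67), while the chromatin remodelling subunit Smarcd3 was lowest at 1.62-fold (1.47 to 1.77). All 10 genes of that list were above 0, with a median of 1.64 and Pharyngeal mesoderm next at 0.38. In Mesenchyme, Ahnak (ENSMUSG00000069833), a large scaffold protein, reached 3.24-fold (3.08 to 3.42), the keratin Krt18 2.89-fold (2.69 to 3.10) and the bHLH factor Hand1 2.89-fold (2.68 to 3.11), and the list had 9 of its 10 genes above 0 and a median of 1.29. Krt18 was higher still in ExE endoderm, and Msx1 was the list's lowest in Mesenchyme at 0.879-fold (0.794 to 0.972). Pharyngeal mesoderm had the weakest list of those led by their own type, a median of 0.33 with 6 of its 8 genes above 0. There Tcf21 (ENSMUSG00000045680), a regulator of pharyngeal muscle, reached 1.67-fold (1.47 to 1.88), the growth factor gene Fgf10 1.53-fold (1.37 to 1.69), Mef2c 1.39-fold (1.25 to 1.53) and Ebf1 0.971-fold (0.901 to 1.05), and with promoter OCRs alone the list was no longer led by this type. Mef2c was higher still in Neural crest.

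Over all nuclei the Somitic mesoderm, Paraxial mesoderm and NMP lists were each highest in the type of that name. In Somitic mesoderm Msgn1 (ENSMUSG00000047002) and Tbx6, which specify unsegmented paraxial mesoderm, stood at 8.66-fold (7.59 to 9.73) and 3.75-fold (3.46 to 4.06), and Mesp2, which sets the boundary of the next somite, at 3.12-fold (2.86 to 3.38). Tcf15 was lowest at 1.24-fold (1.14 to 1.35), and the list median was 1.01 with 10 of its 10 genes above 0. In Paraxial mesoderm the forkhead gene Foxc2 (ENSMUSG00000046714) reached 2.80-fold (2.48 to 3.16), Prrx2 2.49-fold (2.30 to 2.69) and Twist1 1.80-fold (1.67 to 1.94), and Foxc1 was lowest at 1.46-fold (1.37 to 1.56), for a median of 0.75 with 8 of its 8 genes above 0. Prrx2 was higher still in Pharyngeal mesoderm and Twist1 in Neural crest. The tail bud factors Cdx4 (ENSMUSG00000031326) and Nkx1-2 led the NMP list at 4.42-fold (3.99 to 4.87) and 2.67-fold (2.34 to 3.01), followed by Cdx1 at 2.04-fold (1.91 to 2.18), with Wnt3a lowest at 1.43-fold (1.34 to 1.53), a median of 0.93 and 8 of its 8 genes above 0. The NMP list was led by another type among 4n nuclei alone. A list for intermediate and lateral plate mesoderm, for which no annotated type was named, was highest in Mixed mesoderm at 0.38 and in NMP at 0.37, but stood at -0.02 in Mixed mesoderm without promoter OCRs. In Mixed mesoderm Foxf1 stood at 2.02-fold (1.83 to 2.22), Hand2 at 1.53, Prrx1 at 1.4 and Pax2 at 0.853-fold.

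Of Forebrain, Mid/Hindbrain and Spinal cord, Forebrain alone led its own list over all nuclei and OCRs. In Forebrain Lhx5 (ENSMUSG00000029595), Six3 and Hesx1, homeobox genes of the anterior neural plate, stood at 2.26-fold (2.1 to 2.43), 1.92-fold (1.73 to 2.13) and 1.76-fold (1.59 to 1.95). The Forebrain median was 0.60 with 10 of its 10 genes above 0, and the list was led by another type among 2n nuclei. With promoter OCRs alone Hesx1 stood at -0.43 log2 in Forebrain and the list median at 0.32, and without promoter OCRs the median was also 0.32. In Spinal cord Sox1 (ENSMUSG00000096014) reached 2.53-fold (2.32 to 2.76), Sox2 2.05-fold (1.79 to 2.33) and Pax6 1.92-fold (1.80 to 2.04), all neural progenitor regulators, but the posterior gene Hoxb9 was at 0.503-fold (0.428 to 0.586). The Spinal cord list had a median of 0.45 in Spinal cord, with 8 of its 10 genes above 0, and 0.59 in NMP. In Mid/Hindbrain Wnt1 (ENSMUSG00000022997) stood at 1.85-fold (1.68 to 2.02), Hoxa2 at 1.41-fold (1.15 to 1.70) and En2 at 1.32-fold (1.19 to 1.47), with Hoxb1, a segment gene of the hindbrain, lowest at 0.662-fold (0.564 to 0.777). Wnt1 was higher still in Neural crest, Hoxa2 in Somitic mesoderm and En2 in Forebrain. The Mid/Hindbrain list had 9 of its 10 genes above 0 in Mid/Hindbrain and a median of 0.31, below the 0.46 of Spinal cord. In Neural crest Sox10 (ENSMUSG00000033006) and Foxd3, both early crest regulators, stood at 6.5-fold (5.69 to 7.40) and 4.99-fold (4.0 to 6.15) and Pax3 at 2.00-fold (1.85 to 2.15). Snai2, a driver of crest delamination, was at 0.871-fold (0.652 to 1.16), and the Neural crest list had 9 of its 10 genes above 0 and a median of 0.92.

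Epithelial and endodermal lists overlapped between types. In Surface ectoderm Esrp1 (ENSMUSG00000040728), a splicing regulator of epithelia, stood at 3.36-fold (3.17 to 3.57), the epidermal regulator Trp63 at 2.59-fold (2.40 to 2.79), Wnt6 at 2.26-fold (2.11 to 2.43) and the keratin Krt19 at 1.30-fold (1.16 to 1.44), for a median of 0.98 with 10 of its 10 genes above 0. Surface ectoderm also had the highest medians of the short lists for primordial germ cells (0.30, with Dnd1 at 1.70, Prdm1 at 1.48, Pou5f1 at 1.32 and Nanos3 at 1.02-fold) and for trophoblast (0.21, with Ascl2 at 1.69, Tfap2c at 1.56, Elf5 at 1.31 and Hand1 at 0.789-fold). In ExE endoderm the apolipoprotein gene Apoa4 (ENSMUSG00000032080) stood at 29.7-fold (17.5 to 47.7), alpha-fetoprotein, Afp, at 13.3-fold (10.1 to 17.4) and transthyretin, Ttr, at 11.7-fold (9.22 to 14.5), with transferrin, Trf, lowest at 2.29-fold (1.52 to 3.42). That list had the highest median of all, 2.82 with 10 of its 10 genes above 0. A short list for parietal endoderm also had its highest median there, 0.80, with 4 of its 6 genes above 0, Sox7 at 2.05, Sparc at 1.84, Lamb1 at 1.83 and Plat at 0.524-fold, but the median was 0.10 among 2n nuclei, 0.09 without promoter OCRs and -0.29 with promoter OCRs alone. Sox7 and Sparc were higher still in Endothelium and Lamb1 in Notochord. The Gut list had 10 of its 10 genes above 0 in Gut, where E-cadherin, Cdh1 (ENSMUSG00000000303), stood at 2.76-fold (2.57 to 2.96), the pioneer factor gene Foxa2 at 2.03-fold (1.84 to 2.22) and the foregut gene Nkx2-1 at 1.41-fold (1.18 to 1.67). Its median of 0.86 in Gut lay below the 0.95 of ExE endoderm, where Cdh1 and Foxa2 were higher still. In Notochord, Noto (ENSMUSG00000068302) reached 3.11-fold (2.43 to 3.98), Chrd, which encodes the BMP antagonist chordin, 2.60-fold (1.75 to 3.72) and the ventral signal Shh 2.59-fold (1.95 to 3.43), with the ciliary regulator Foxj1 lowest at 1.31-fold (0.809 to 2.11). The Notochord list had 10 of its 10 genes above 0 and a median of 1.15, and Notochord nuclei had the highest median doublet score of all types, 0.281, ahead of 0.176 in Mixed mesoderm.

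In all, 14 of the 17 lists named after a type were led by that type, as the map of list medians shows, and each own median lay at or above percentile 99.99 of 10000 random lists matched in size and read count. Lists for cells without an annotated type also lay high in the type where each was highest, from 98.92 for trophoblast to 99.84 for megakaryocytes and macrophages. A high percentile therefore does not identify a type. The types were defined by the authors on the same reads, so a list led by its own type is not independent evidence for the type. The 3 other calls depend on the setting. Gut led its own list with promoter OCRs alone, with the other OCRs alone, with CPM over promoter OCRs and among 2n nuclei, Spinal cord with promoter OCRs alone and among 4n nuclei, and Mid/Hindbrain among 2n nuclei.

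**Figure D2:**
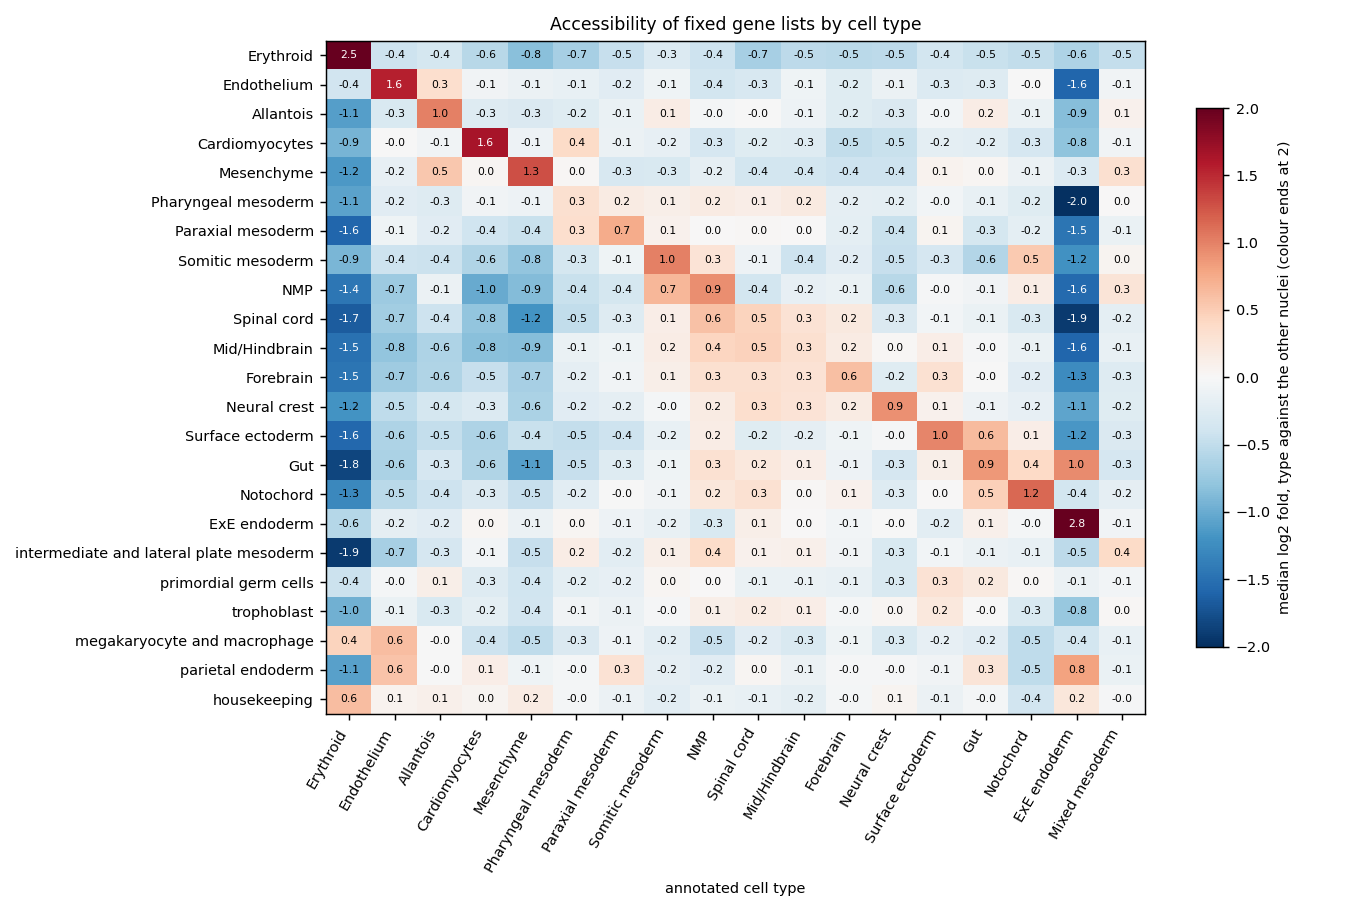
Median log2 fold of each gene list (vertical) in each annotated cell type (horizontal) against all other nuclei, from CPM summed over the OCRs of each gene. The own type is highest for 14 of 17 lists, from 0.33 in Pharyngeal mesoderm to 2.82 in ExE endoderm.

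Transcription factor motifs gave a parallel view, through the authors' chromVAR scores, which compare reads at OCRs with a motif to a background of like OCRs. GATA motifs, bound by factors of blood, heart and endoderm, differed most in Erythroid nuclei, which scored 6.04 above the rest (SD over nuclei 3.10 in Erythroid and 3.15 in the rest). Within Erythroid the mean score was 3.63 in the third of nuclei with the lowest share of reads in peaks (median 33.3%) and 7.80 in the highest (59.2%). Cardiomyocytes followed with a difference of 4.55 at a median share of 32.1%, the 2 types were not compared at equal shares, and NMP were lowest at -3.23. The KLF group, with the red cell factor Klf1, was highest in Erythroid at 2.15. The TAL group was not, standing at -0.51 in Erythroid and 1.81 in Notochord. ETS motifs, the targets of endothelial regulators such as Etv2 and Erg, stood at 4.19 in Endothelium (SD 2.06), where AP1 motifs were also highest at 3.19. SOXF motifs led there by a narrow margin, 0.54 against 0.52 in Mid/Hindbrain, and lost that lead with the median over nuclei and among 2n and 4n nuclei. Single motifs with the highest scores were Gata1 in Erythroid (6.43), Gm4881 (9.85), Elf1 and Etv2 in Endothelium, and Gata4 in Allantois (3.24), Cardiomyocytes (4.88) and Pharyngeal mesoderm (4.32).

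In the remaining mesoderm, MEF2 motifs, bound by activators of muscle genes, stood at 3.37 in Cardiomyocytes, and HAND motifs at 3.06 in Mesenchyme. TEAD motifs, the outlet of Hippo signalling, showed the largest difference of any group, 6.52 in Mesenchyme (SD 4.12), ahead of Gut at 2.89. CDX motifs stood at 4.73 in NMP, and posterior HOX motifs were highest in NMP at 3.78 rather than in Allantois, at 2.37. The T motif was highest in Somitic mesoderm at 2.74 and stood at 0.20 in NMP. FOXC motifs were highest in Gut (2.57) ahead of Paraxial mesoderm (2.36), and TWIST motifs in Somitic (1.26) ahead of Paraxial mesoderm (1.13). PITX motifs were highest in Forebrain at 2.60 and stood at -0.51 in Pharyngeal mesoderm. Leading single motifs were Hoxa9 in NMP (5.55) and Mixed mesoderm (2.71), Tbx20 in Somitic mesoderm (5.11), Tcf21 in Paraxial mesoderm (2.76) and Tead3 in Mesenchyme (6.72).

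In neural and ectodermal types OTX and LHX motifs were highest in Forebrain, at 1.35 and 1.42. SOXB1 motifs, bound by neural progenitor factors, stood at 1.95 in Mid/Hindbrain and 1.89 in Spinal cord, and POU3 motifs were highest in Spinal cord at 0.92 with Mid/Hindbrain at 0.16. SOXE motifs were highest in Mid/Hindbrain at 1.56, above Neural crest at 1.39. TFAP2 and GRHL motifs stood at 3.39 and 4.05 in Surface ectoderm, and TFAP2 also at 2.76 in Neural crest. The P63 motif was highest in Mesenchyme (0.86), with Surface ectoderm next (0.48). In endoderm HNF4 motifs, bound by regulators of lipid transport, stood at 4.70 in ExE endoderm and 0.42 in Gut. FOXA motifs were at 3.51 in Notochord and 3.48 in Gut, and the NOTO motif at 1.18 in Forebrain against 0.18 in Notochord. CTCF, taken as a control, was highest in Erythroid at 1.12, stood at 0.99 in Forebrain and was lowest in Spinal cord at -1.69. The control was thus not level across types, and small leads, such as those of OTX, LHX and SOXF, are to be read against that spread. Leading single motifs included Hnf4g in ExE endoderm (7.76), Foxa1 in Notochord (5.02) and Gut (4.84), Grhl1 in Surface ectoderm (4.05), Tfap2a in Neural crest (2.93), Hoxb1 in Spinal cord (4.03), Sox2 in Mid/Hindbrain (3.24) and Gsc2 in Forebrain (3.03). The own type was highest for 12 of the 25 groups that had a named type and a motif. Related factors bind like motifs, so a score does not tell which factor was bound, and FOXA was led by Gut among 2n nuclei.

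**Figure D3:**
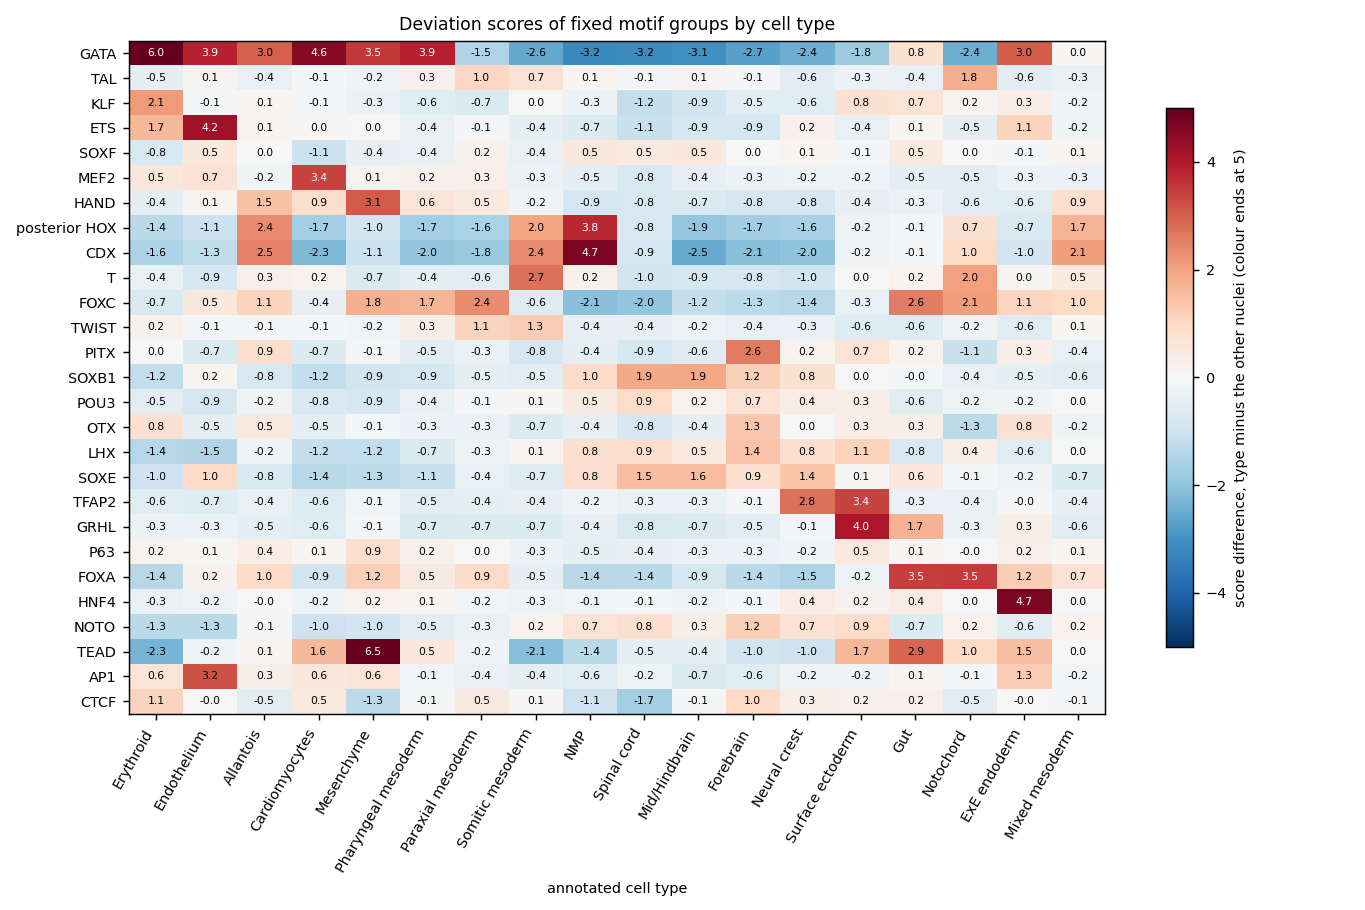
Difference in chromVAR score between the nuclei of each annotated type (horizontal) and all other nuclei, as the median over the motifs of each group (vertical). GATA reaches 6.04 in Erythroid and TEAD 6.52 in Mesenchyme.

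Leading OCRs are given by type (positions in GRCm38, folds in CPM against all other nuclei together, so that another single type can come near). They were picked for their fold on the reads from which the types were defined, and the intervals do not cover that choice. An intergenic OCR paired with Apob, an apolipoprotein gene (chromosome 12, 8017945 to 8018445), stood 119.7-fold higher in ExE endoderm (76.6 to 187), with a read in 20.5% of nuclei. An OCR paired with S1pr1, a receptor that stabilises vessels (chromosome 3, 115709007 to 115709583), was 70.3-fold higher in Endothelium (52.7 to 95), and a Mef2c intron (chromosome 13, 83583858 to 83584377) 47.4-fold higher in Neural crest (35.6 to 63.3). An OCR paired with Tbx4 (chromosome 11, 85946166 to 85946666) led Allantois at 26.7-fold (19.4 to 36.7). The leading OCR of Mesenchyme lay in a Stard8 intron (chromosome X, 99038574 to 99039074; 36.3-fold), that of Pharyngeal mesoderm in an Itga9 intron (chromosome 9, 118660137 to 118660643; 20.7-fold), that of Gut in a Pacsin2 intron (chromosome 15, 83411473 to 83412029; 26-fold) and that of Forebrain in an Otx2os1 intron (chromosome 14, 48738110 to 48738610; 20.8-fold). Surface ectoderm had a Lmntd1 intron (chromosome 6, 145478871 to 145479371; 30.3-fold) and Mixed mesoderm the lowest leading OCR, a Usp29 intron (chromosome 7, 6744515 to 6745027; 9.04-fold). In 7 further types the leading fold ran from 20.2 in NMP to 51.6 in Spinal cord. The authors call the Itga9 OCR specific in Cardiomyocytes as well, and the Usp29 OCR in Pharyngeal mesoderm and Mesenchyme as well.

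By the rule of a read in at least 5% of a type's nuclei and at least 4-fold higher CPM than in all other nuclei, 24540 OCRs (8.04%) were type-specific, 21383 of them in 1 type. Few were promoters, with 5.07% at a TSS against 18.7% of all other OCRs and 43.6% of those other OCRs that were read in at least 5% of a type's nuclei, while 51.2% lay in introns and 37.9% were intergenic against 43.9% and 28.8%. Endothelium had the most, 3068, then Notochord with 2898 and ExE endoderm with 2736, and Mixed mesoderm the fewest with 208. After thinning to the same nuclei and reads ExE endoderm led instead with 2907, ahead of Endothelium with 2716, and Mixed mesoderm, still the fewest, had 571. The authors' own calls order the types otherwise, with 2728 in Spinal cord, the most, 2492 in Endothelium, 588 in Mixed mesoderm, 354 in ExE endoderm and 149 in Notochord, the fewest. Shared OCRs were set against independent draws from the 54569 OCRs read in at least 5% of the nuclei of some type. On this base some neighbouring lineages shared more OCRs specific by the rule than such draws would give, and others fewer. Draws from all 305187 OCRs would give smaller expected numbers, so a count called fewer depends on the base. Mid/Hindbrain and Spinal cord shared 334 (41.1 if independent), Cardiomyocytes and Pharyngeal mesoderm 230 (37.2), ExE endoderm and Gut 228 (56.9) and Gut and Notochord 224 (60.2). Fewer were shared by Paraxial and Somitic mesoderm, 11 (24.7), and by NMP and Somitic mesoderm, 10 (26.1). NMP and Spinal cord shared 32 (36.9), and Allantois and Endothelium 30 (62.4). Other pairs also lay below the expected number, such as Forebrain and Gut with 0 (17.5) and Endothelium and Somitic mesoderm with 1 (78.0). A low count was thus not particular to neighbouring lineages. Counts of rare types lean on few nuclei. The Notochord count was 1207 when the rule had to hold in both of 2 sets of tagmentation barcodes, with a median fold of 3.87 in the even set for OCRs chosen in the odd set. When a 4-fold excess over the highest other type was asked for, the total was 4973. These ranged from 1101 in ExE endoderm to 12 in Mid/Hindbrain and 0 in Mixed mesoderm.

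**Figure D4:**
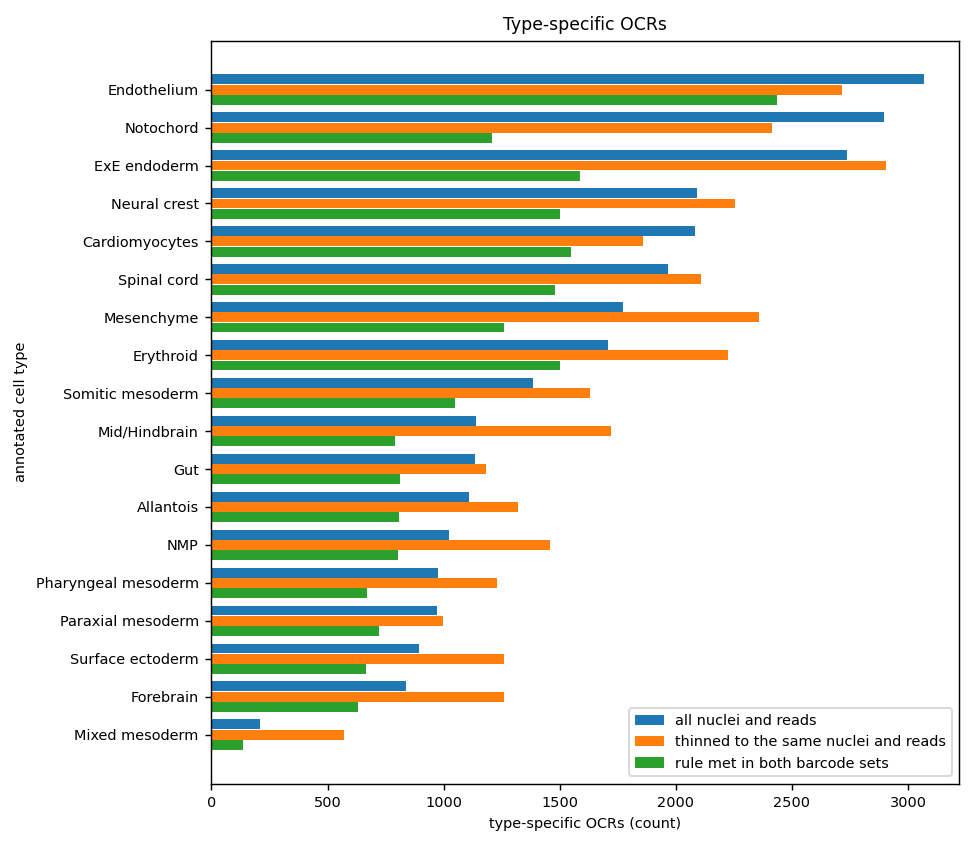
Number of type-specific OCRs in each annotated type, with all nuclei and reads, after thinning every type to 135 nuclei and 791687 reads, and when the rule held in both barcode sets. Endothelium has 3068, 2716 and 2434, Notochord 2898, 2415 and 1207, and ExE endoderm 2736, 2907 and 1586.

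Pairs of related types were then compared directly, each ratio or score difference being that of the type named first to, or minus, the other. Between NMP and Spinal cord, which share an origin, the posterior gene Hoxb9 had 5.17 (4.41 to 6.10) times the CPM in NMP, Hoxb8 4.90 (4.13 to 5.82) times and Cdx4 6.34 (4.76 to 8.61) times, while Sox1 stood at a ratio of 0.636 (0.569 to 0.712) and Irx3 at 0.618 (0.555 to 0.687). CDX motifs scored 5.08 higher in NMP, and 1211 OCRs were at least 4-fold higher in NMP against 1586 in Spinal cord. Against Somitic mesoderm, NMP had less Msgn1 (ratio 0.243 (0.199 to 0.294)) and Mesp2 (0.369 (0.322 to 0.422)) and more Nkx1-2 (2.12 (1.73 to 2.60)), with 750 and 1159 OCRs, and T motifs differed by -2.33. Somitic mesoderm exceeded Paraxial mesoderm 12.8 (8.84 to 18.5) times for Msgn1 and 4.64 (3.91 to 5.55) times for Tbx6, while Foxc2 stood at 0.409 (0.336 to 0.494), FOXC motifs differed by -2.77 and 1840 and 1017 OCRs passed. Forebrain and Mid/Hindbrain were the most alike of the 11 pairs, with 228 and 411 OCRs, Hesx1 2.09 (1.69 to 2.58) times higher in Forebrain and Hoxa2 at a ratio of 0.262 (0.190 to 0.365). Of the 10 Mid/Hindbrain genes 6 were higher in Mid/Hindbrain, and Pax2, of the same list, was 1.73 (1.56 to 1.92) times higher in Forebrain. Mid/Hindbrain and Spinal cord differed at 120 and 831 OCRs, and 3 of the 10 Mid/Hindbrain genes were higher in Mid/Hindbrain.

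For thinning, each pair was brought to its own number of nuclei and reads, so thinned counts are not comparable across pairs. Endothelium and Erythroid differed at 3869 OCRs higher in Endothelium and 1400 in Erythroid (2838 and 1408 after thinning to 803 nuclei each). Without thinning these were the most of the pairs, but not at 2-fold. Emcn, which encodes an endothelial sialomucin, stood at a ratio of 19.0 (7.78 to 60.5) and Hba-x at 0.0257 (0.0160 to 0.0409), whereas Tal1 did not separate them, at 0.996 (0.908 to 1.09). Endothelium and Allantois differed at 2830 and 1504 OCRs, with Tek at 5.29 (4.26 to 6.55), Tbx4 at 0.317 (0.279 to 0.360), ETS motifs differing by 3.81 and posterior HOX motifs by -3.12. Cardiomyocytes exceeded Pharyngeal mesoderm 11.1 (7.97 to 15.5) times for Actc1 and 10.9 (8.12 to 14.9) times for Myh6, with 922 and 567 OCRs, and Tbx5, a regulator of the heart tube, stood at 0.997 (0.853 to 1.16). Gut and ExE endoderm had Cdh1 at 0.957 (0.764 to 1.21) but Apoa4 at 0.0527 (0.0244 to 0.113) and Shh at 3.28 (1.71 to 7.24), with HNF4 motifs differing by -4.26 and 1780 and 1994 OCRs. Gut and Notochord differed at 975 and 2489 OCRs (1583 and 2957 after thinning to 135 nuclei each), with T at 0.447 (0.354 to 0.569). Neural crest and Surface ectoderm differed at 1974 and 1101 OCRs, with Foxd3 at 5.46 (3.97 to 7.5), Esrp1 at 0.293 (0.239 to 0.357) and GRHL motifs differing by -3.79.

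The OCRs with the highest ratios lay mostly in introns or between genes. An OCR at chromosome 9, 32901224 to 32901725, had a read in 16.8% of Endothelium nuclei and in none of Allantois. Set against a floor of 3 counts it was 84.0-fold higher, and the lower end of its interval was 33.8-fold. An OCR in an Lrp5 intron (chromosome 19, 3632688 to 3633229) was 42.7-fold higher in Somitic mesoderm than in NMP (18 to 133), and an OCR in a Sema3a intron (chromosome 5, 13384465 to 13384965) 25-fold higher in NMP (12.7 to 50.2). A Gli3 intron (chromosome 13, 15602504 to 15603350) was 22.2-fold higher in Gut than in ExE endoderm (3.95 to 881), and a promoter of the transporter gene Abcc2 (chromosome 19, 43781693 to 43782378) 109-fold higher in ExE endoderm (28.1 to 485). Across the 11 pairs there were 30558 calls, an OCR counting once for each pair in which it passed, and 62094 with a fold of 2. Of the motif group comparisons, 24 of 32 were higher in the named type. Pairs with few nuclei, such as Notochord, carry wide intervals.

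The authors also described each nucleus as a mixture of 100 topics, groups of OCRs that open together. ExE endoderm and Erythroid nuclei had the largest shares in a leading topic, with 30.4% (SD over nuclei 7.63) of their mixture in topic 31 and 29.6% (SD 7.33) in topic 82, against 0.572% and 0.457% in all other nuclei. Endothelium had 19.5% in topic 36 and 0.263% elsewhere, the highest ratio of all types at 74.2, Mesenchyme 14.2% in topic 20, Cardiomyocytes 14.0% in topic 11, Notochord 12.7% in topic 58, Neural crest 12.3% in topic 37 and Allantois 12.1% in topic 95. Gut had 10.3% in topic 48 and Surface ectoderm 10.0% in topic 17. The leading topics of the trunk and neural types held less, with topic 61 at 9.43% in Spinal cord, topic 84 at 8.30% in Mid/Hindbrain, topic 97 at 8.21% in Somitic mesoderm, topic 79 at 7.81% in Paraxial mesoderm and topic 100 at 7.73% in NMP. Pharyngeal mesoderm had 7.04% in topic 59, Forebrain 6.32% in topic 62 and Mixed mesoderm 4.07% in topic 73. Of all topics, 38 were at least 4 times higher in some type than in the other nuclei, and each of the 18 types led at least 1. Topics and types come from the same reads, so this is a description of the deposited mixture.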

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

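The comparison of median doublet scores between the 2n and 4n labels was chosen after its result was seen, and the demand that intervals exclude 1 was added to the depth test below after its result was seen.

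Barcodes without a cell type are data that no comparison of the types uses. They held 36359798 reads in OCRs. Any set of barcodes with reads would be listed here, as there are no control samples to set them against, so the listing is no test. Of these reads 0.681% (0.677 to 0.685%) lay in OCRs specific to Cardiomyocytes, against 0.647% in annotated nuclei of all types and 4.18% in Cardiomyocytes themselves. Cardiomyocytes had the highest ratio to annotated nuclei, 1.05, and NMP the lowest, 0.669. TSS OCRs took 34.1% of their reads and 39.6% in annotated nuclei.

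Nuclei labelled 4n held more ExE endoderm and less Notochord, Gut and Cardiomyocytes than those labelled 2n. Against a filter on depth as the whole cause, 3 of the 4 types still passed the rule among nuclei with at least 5000 reads, which met the bound set for it, with ratios of 2.04 (0.843 to 5.42) in ExE endoderm, 0.252 (0.0730 to 0.703) in Notochord and 0.632 (0.477 to 0.833) in Gut. Cardiomyocytes no longer passed, at 0.791 (0.553 to 1.13), and since only Notochord and Gut excluded 1 the counts are too few to decide for the 4 types together. Pairs of nuclei sharing a barcode stay open too, as the median doublet score was higher under 4n in 11 of 15 types, between the bounds of 12 and 9 set for and against it. Sorted plate and label cannot be told apart, and a difference in DNA content or cell size between types may also contribute, which was not tested.

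Notochord and Mixed mesoderm nuclei had the highest doublet scores. If 2 nuclei often shared a barcode, nuclei in the upper part of the score should be deeper, and the lower of the 2 ratios of median reads, upper to lower part, was 1.195 in Mixed mesoderm, with 1.32 in Notochord and a median of 1.28 over the 18 types. These lie between the bounds of 1.2 in both types, against, and 1.5 in both, for, so shared barcodes remain possible. The Notochord list median was 1.13 among Notochord nuclei in the lower part of the score and 1.15 over all of them. This met the bound set against a profile that rests on nuclei with high scores. The parts were split at the Notochord median of 0.281, above the median of every other type. The lower part can thus hold high scores too, and the type was named from the same reads, so the split cannot decide this. No biological explanation was tested, since the design has no group for it.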

How the results depend on the processing

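No paired analysis was possible because all gates and runs come from 1 pool, and all alternatives listed among the methods were run. No median of the 17 lists named after a type changed sign under an alternative, but among the 6 other lists 2 did, parietal endoderm in ExE endoderm with promoter OCRs alone (-0.29) and intermediate and lateral plate mesoderm in Mixed mesoderm without them (-0.02). Single genes were less stable, as 17 of 162 entries of genes in the 17 lists had the other sign with promoter OCRs alone, among them Fgf10 (-0.84 log2) and Hesx1 (-0.43). Others kept their sign but changed in size either way. Alas2 fell from 3.55 to 0.92 log2 and Trp63 from 1.35 to 0.03, whereas Klf1 rose from 1.75 to 3.51. The number of lists led by their own type ran from 14 to 15, the number of motif groups from 11 to 12 and the number of topics from 26 to 48, and the number of types past the rule for labels from 3 to 4 apart from the bound of 2, under which it was 2. The ratio of median reads, 4n to 2n, was 1.33 in autosomal OCRs and 1.32 as OCRs with a read. Type-specific OCRs numbered 66858 with 2% of nuclei, 6075 with 10%, 37593 at 2-fold, 11577 at 8-fold and 4973 against the highest other type, and calls over the pairs 62094 at 2-fold. These follow from looser or stricter bounds. Other alternatives gave between 17747 (both barcode sets, added after seeing the data) and 27878 (thinned) type-specific OCRs. Of 187 list medians under alternatives, 95 moved further than a bound taken from the counting interval of the list's summed reads over all nuclei. That interval is not one of the median and leaves out the smaller counts of an alternative such as a single label. A move past it thus need not exceed counting error, and the cause of these moves was not tested. Depth limits the rarest types most, with 983217 reads in ExE endoderm and 1288851 in Notochord.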

Other observations

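The authors divided Allantois, Endothelium and Erythroid into subclusters, which cover the allantois, vessels and blood. This comparison, its genes and the RUNX motif group were chosen after the tables were seen. The subcluster Al_EC, 231 nuclei of which 205 are annotated Endothelium and 26 Allantois, had some vessel features and some of the allantois. Its ETS motifs scored 3.80 (SD over nuclei 2.12), between the 3.23 of EC1 and the 5.13 of EC2, whereas Al1 to Al4 lay between -0.01 and 0.24. Posterior HOX motifs lay between both sides, at 0.24 in Al_EC, 1.32 to 3.26 in Al1 to Al4 and -1.39 and -1.65 in EC1 and EC2. The allantoic gene Tbx4 had 139 (118 to 163) CPM in Al_EC, 240.0 (207 to 276) in Al1, 381 (331 to 436) in Al4, 89.7 (74.5 to 107) in EC1 and 65.3 (50.0 to 85.2) in EC2. The VEGF receptor gene Kdr had 223 (196 to 254) in Al_EC, 85.2 (66.8 to 109) in Al1, 159.9 (139.7 to 183) in EC1 and 330.5 (294 to 371) in EC2, Etv2 101 (82.9 to 122) in Al_EC, 69.5 (56.5 to 85.4) in EC1 and 80.1 (63 to 102) in EC2, and Tal1, a regulator shared by blood and vessel, 197 (172 to 225) in Al_EC, 202 (179 to 228) in EC1 and 74.0 (56.9 to 96.1) in Al1. The vessel genes Cdh5 and Tie1 were nearer to the allantois, Cdh5 at 33.5 (23.9 to 46.7) in Al_EC, 26.1 (16.2 to 39.9) in Al1 and 81.6 (67.1 to 98.3) in EC1, and Tie1 at 41.2 (30.1 to 55.2), 29.8 (19.1 to 44.4) and 87.9 (73.1 to 105).

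EC_Haem, 86 nuclei all annotated Endothelium, was not set apart clearly by the blood genes read. Its ETS score was 3.43, below that of EC2, and RUNX motifs, bound by regulators of blood cell emergence, scored 1.18 there, 0.22 in EC1, 0.73 in EC2 and 1.22 to 2.80 over the 9 erythroid subclusters. Runx1 had 241 (186 to 306) CPM in EC_Haem, 178 (156 to 202) in EC1, 197 (169 to 229) in EC2 and 344 (301 to 394) in Ery7, so the intervals of EC_Haem and EC2 overlap. Tal1 had 252 (196 to 318) in EC_Haem and 264 (232 to 301) in EC2, and Erg, an endothelial regulator, 277 (218 to 347), 149 (129 to 171), 209.5 (181 to 243) and 46.7 (32.1 to 67.8) in EC_Haem, EC1, EC2 and Ery7. Gata1 had 32.8 (15 to 62.3) in EC_Haem, 11.8 (6.72 to 19.1) in EC1, 1.14 (0.0288 to 6.33) in EC2 and 26.4 (15.3 to 45.1) in Al4, and Alas2 29.2 (12.6 to 57.5), 5.88 (2.54 to 11.6) and 1.70 (0.275 to 8.21) in the first 3 and 18.2 (10.4 to 29.6) in Al2, so EC_Haem was above EC2 in both genes but overlapped an allantoic subcluster, while Klf1 had 21.9 (8.03 to 47.6) in EC_Haem and 17.0 (9.53 to 28.1) in EC2. The globin gene Hba-x stood at 14.6 (3.97 to 37.4) in EC_Haem, 6.25 (3.03 to 12.6) in EC1, 0 (0 to 4.19) in EC2, 138 (115 to 165) in Ery1 and 343 (298 to 393) in Ery4. GATA motifs scored 3.38 in Ery1 and 9.20 in Ery7, the lowest and highest of the erythroid subclusters. Of the 12 OCR patterns that the authors number for endothelium, 6 had their highest CPM in EC2, in 5 of them with EC_Haem next, and 4 in Al4. These 3 subclusters also have the highest median shares of reads in peaks among the allantoic and endothelial ones, 49.6%, 49.8% and 51.9%, and the patterns were not compared at equal shares.

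GATA scores also differed within lineages, from 1.02 in Al1 to 7.496 in Al4, from 2.73 in EC1 to 5.41 in EC2 and from 3.38 in Ery1 to 8.39 in Ery4, 3 pairs of subclusters picked after their scores were seen. Ery7, with the highest erythroid score, was not in the pairs. Read depth as the whole cause is argued against by like median reads in OCRs. They were 6710 in Al1 and 7532 in Al4, 7600 in EC1 and 7708 in EC2, and 4812 in Ery1 and 5115.5 in Ery4. Matching nuclei on reads could thus change little, and the GATA difference kept 98.7% in Allantois, 99.2% in Erythroid and 107% in Endothelium. The share of reads in peaks, a median of 28.9% in EC1 and 49.6% in EC2, remains a candidate source of part of it. GATA scores also differed between some subclusters of like median share, without matching on reads. They were 1.02 in Al1 (27.9%) and 3.47 in Al2 (29.2%), and 5.61 in Ery2 (57.0%) and 8.39 in Ery4 (58.8%). EC2 (49.6%) and EC_Haem (49.8%) differed less, at 5.41 and 4.67. Nuclei of EC1 and EC2 matched on that share kept 34.1% of the difference in 36 pairs, and Allantois and Erythroid gave only 5 and 4 pairs, under the 20 asked for. Whether the subclusters are developmental steps was not tested, since the design has 1 stage.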
